A study of Homo sapiens with 2 samples.

How the data were processed

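RNA was taken from untreated HEK293T cells with TRIzol and treated with DNase I, per the labels' protocols. First-strand cDNA was primed with oligo(dT), the remaining RNA and primers were digested with a nuclease, and the cDNA was sheared and built into libraries with a single-strand ligation kit, per the same protocols. The primer favours RNAs with a poly(A) tail, so levels of RNAs without one are not levels in the cell. The deposited files hold raw counts per Ensembl gene, 1 library per file, which the authors did not normalise, per the file headers and the whole-number values. The submitters' processing notes name bcl2fastq 2.17, Trim Galore 0.6.7, featureCounts 2.0.3 and build GRCh38. The aligner, the annotation release and the strand and overlap settings are not given in the sources used here. The gene coordinates and exon lengths are those of the deposited files, and the annotation columns were identical in both.

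Both files list 60664 genes, and 60463 IDs matched a symbol. Gene types and sequences came from GENCODE 29 on the same build, which holds 58396 of the IDs and types 19890 as protein-coding. Overlap of exons was computed from the deposited coordinates with bedtools 2.31.1. Of all genes, 18470 share exonic bases with another gene and 7374 share 25% or more. The overlap setting was checked on the counts. There were 837 pairs in which 1 gene, 824 genes in all, lies wholly inside exons of a gene on the opposite strand. The inner gene had counts in replicate 1 in 523 pairs and exceeded the outer gene in 0, against a median of 222 pairs when the outer genes were shuffled. MIF and the opposite-strand MIF-AS1 both had 68258 counts in replicate 1. The counts therefore behave as if reads were given to each overlapping gene whatever its strand, so overlapping and antisense genes are treated as uncertain. This holds also where the overlap of a named gene is not given beside its value. Genes with near-identical copies, such as U2AF1, HSPA1A and SMN1, are uncertain for another reason, since a read from such a copy also aligns to the other.

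CPM was computed here from the deposited counts and their totals, and TPM from the counts and the deposited exon lengths, without a normalisation between libraries. The deposited length merges all annotated exons of a gene, so the order of a list's members by TPM depends on it. Replicate 1 held 18011638 counts and replicate 2 held 18575058. Shares of counts carry exact 95% binomial intervals in the tables, and a count of 0 was read as allowing up to 3 counts. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene was called detected at 1 CPM or more in both libraries.

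Ratios between the libraries are log2 of replicate 2 over replicate 1 with TMM factors (1.01 and 0.989) and a prior count of 2, from edgeR 4.0.16 in R 4.3.3. They were counted over genes with a mean count of 50 or more. The spread was edgeR's biological coefficient of variation over 18315 genes passing its default filter, with an intercept alone. DESeq2 1.42.0 size factors were an alternative. They were 1 and 1, because the median ratio fell among genes with equal counts. The labels give 1 group, so no test between groups was run.

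In all, 38 gene lists were fixed before the data were examined, as were 8 list pairs, the tests and the alternatives in the closing section except where stated. The level of a list was the median of log2(TPM + 0.1) over its protein-coding members, compared with 100000 random lists of the same size from all protein-coding genes, two-sided, with Benjamini-Hochberg adjustment over 35 lists. List pairs were compared by permuting membership 100000 times, or exactly with fewer than 10 members, adjusted over 8 pairs. Genes in a list are not independent replicates, so these p-values describe how the lists lie among genes in these libraries. Ratios of lists between the libraries were placed among 10000 random lists matched on mean expression in 20 bins. These random lists held protein-coding genes alone, also for lists with noncoding members. Lists of noncoding RNAs had no random-list test of their level.

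Named genes followed a rule fixed beforehand. It took the 2 highest and 2 lowest members of each list by mean TPM, with ties broken by symbol, and all members of the ribonuclease H, helicase, topoisomerase and assay locus lists. It also took the 10 most counted genes and the 10 protein-coding genes with the largest ratios in each direction at a mean count of 50. Genes outside this rule are said to be so. Some genes that the rule takes are not reported here, though they remain in the counts and medians of their lists.

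The steps were tested on simulated data. For the gene ratios, over 14704 genes, a simulated coefficient of variation of 10% was recovered as 9.87%, and 50% of genes changed 2-fold, 100% of those changed 4-fold and 0.0483% of unchanged genes passed 1 log2. For list levels, over 19890 genes, 82% of lists of 20 raised by 3 log2 and 2% of unchanged lists had p under 0.05. For list pairs, 65.5% of pairs of 15 genes parted by 4 log2 and 3% of unchanged pairs did. For list ratios, 3.5% of random lists of 20 fell in the outer 2.5% on either side.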

Results

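RNA from untreated HEK293T cells was measured in 2 RNA-seq libraries. HEK293T is an established human line made from embryonic kidney cells with adenovirus DNA and the SV40 large T antigen. The libraries belong to a study of R-loops, structures in which an RNA strand pairs with 1 strand of the DNA duplex and displaces the other. The labels give 1 group of 2 replicates and no contrast, so the comparisons below are between groups of genes within the libraries and between the replicates. The cell line entry of replicate 2 differs from its own title by 1 digit and was read as HEK293T, following the title. Assigned counts totalled 18011638 in replicate 1 and 18575058 in replicate 2, over 60664 genes on build GRCh38. At these depths a count of 0 allows up to 0.167 CPM (counts scaled to a common library total) in replicate 1 and 0.162 CPM in replicate 2. Values after ± are the SD over the libraries (n = 2). The labels do not say that the libraries came from separate cultures, so the spread between them may be technical.

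Ribosomal protein and mitochondrial transcripts led both libraries. The 65 cytosolic ribosomal protein genes held 15.3% ± 0.48 of the counts and the mitochondrial genome held 2.42% ± 0.0977. The 10 most counted genes included RPS2, EEF1A1, MT-CO1, RPS6, RPL13A, RPS18, RPL13, RPS3A and RPL10, and all 10 together held 5.41% ± 0.149. RPL10 shares 53.4% of its exonic bases with other genes and RPS2 25.9%, so their values are uncertain. RPS2, at chromosome 16 from 1962058 to 1964841, had 139917 counts in replicate 1 and 163754 in replicate 2. EEF1A1, the translation elongation factor, had 134111 and 154882. MT-CO1, a cytochrome c oxidase subunit of the mitochondrial genome, had 114312 and 117371.

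At 1 CPM or more in both libraries, 16801 genes were detected, of which 13112 were protein-coding. These were 65.9% of the 19890 protein-coding genes in the files. A further 547 genes reached 1 CPM in replicate 1 alone and 498 in replicate 2 alone. Genes of the protein-coding type held 90.5% ± 0.353 of the counts, genes of the antisense type 4.15% ± 0.124 and long intergenic noncoding genes 0.854% ± 0.0739. Of the antisense counts in replicate 1, 98.1% came from genes that share exonic bases with another gene and 78.6% from genes that share 25% or more, so most of these counts are uncertain as to strand.

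The replicates were close for most genes, and those that parted were mostly lower in replicate 2. Across 21018 genes with 10 or more counts in total, Pearson's r of log2(CPM + 1) was 0.989 and Spearman's rho 0.985. These are descriptions across genes, which are not independent replicates. The chi-square per degree of freedom was 12.7, so the libraries differed by more than counting noise and were kept as separate samples. The common biological coefficient of variation was 15.6%, from edgeR with 1 residual degree of freedom, and its trend ran from 19.7% under 50 counts to 11.2% in the highest class of counts.

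Of 14704 genes with a mean count of 50 or more, 282 were lower and 21 were higher in replicate 2 by 1 log2 or more. These counts became 164 and 31 after centring on transcript GC content, an alternative chosen after seeing the data, 562 and 214 at a mean count of 10 or more, 154 and 2 at 200 or more, and 2257 and 1172 with no filter. The ratios of 88.3% of the genes lay within 0.5 log2 and those of 97.9% within 1. OSBPL8, a lipid transfer protein gene on chromosome 12, fell furthest among the protein-coding genes, from 747 counts to 89 (log2 ratio -3.05). FAM171B had 137 and 16 counts (-2.96), PABPC4L 245 and 36 (-2.71), PARD6B 87 and 13 (-2.58) and CLVS1 195 and 33 (-2.51). CACNA2D1 (-2.36), HIPK3 (-2.34), SP4 (-2.33), SPIN4 (-2.31) and ZNF483 (-2.21) followed. Among genes higher in replicate 2, PEAK3 on chromosome 19 had 0 counts in replicate 1 and 153 in replicate 2. Against the 3 counts that a count of 0 allows, this was at least 49.5-fold higher. ENSG00000285868 (1.40), NT5DC4 (1.39), C17orf113 (1.23), ATF7-NPFF (1.17) and AKNAD1 (1.02) also passed 1 log2, and ATP2A3 (0.96), TNFRSF21 (0.96), C22orf15 (0.95) and MIURF (0.94) did not. ENSG00000285868, ATF7-NPFF and MIURF share much of their exonic sequence with other genes, so their counts are uncertain. With 1 library on each side these ratios have no replicate check and no p-value.

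**Figure D1:**
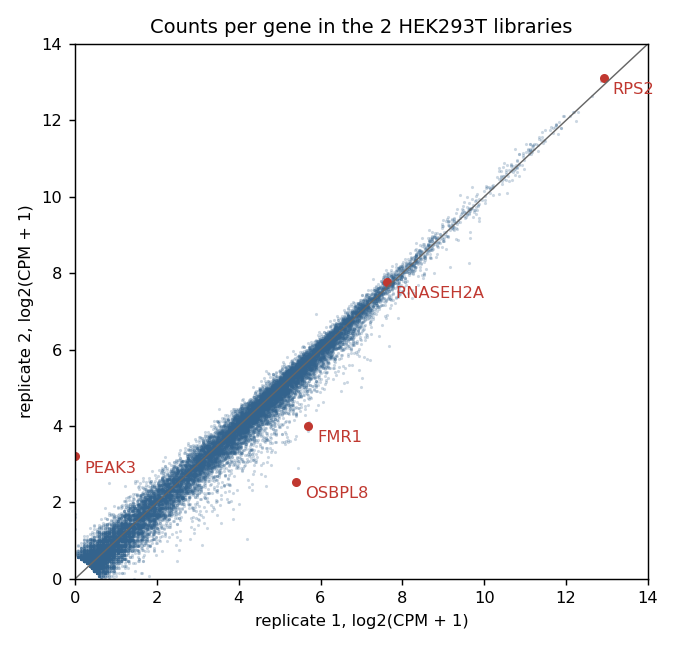
Each point is 1 of the 21018 genes with 10 or more counts in total, with log2(CPM + 1) in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, and the line marks equal values. Named genes are in red, and OSBPL8 (747 and 89 counts) lies below the line while PEAK3 (0 and 153 counts) lies on the vertical axis.

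Factors that remove or prevent R-loops were all detected, 36 of 36. Their median was 17.2 TPM (counts corrected for exon length and scaled to a common total), with 16.8 in replicate 1 and 16.7 in replicate 2, against 2.88 TPM for all protein-coding genes. They ranged from TDRD3 (2.79 ± 0.0164 TPM) and BRCA2 (2.82 ± 0.0989) to DDX5 (181 ± 14.1) and RNASEH2A (203 ± 9.86). The list lay above random protein-coding lists of its size (adjusted p = 0.00045, two-sided random-list test). Among genes detected in both libraries alone, the difference was 1.00 log2 with adjusted p = 0.0687. The 36 genes took 0.448% ± 0.00771 of the counts.

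The ribonucleases H, which cut the RNA strand of RNA-DNA hybrids, had a median of 80.6 TPM, midway between the 2 middle members of 4. On the tested scale of log2(TPM + 0.1) the median was 5.42, or 3.84 above the protein-coding median (adjusted p = 0.0357, random-list test). RNASEH2A, the catalytic subunit of ribonuclease H2 at chromosome 19 from 12806584 to 12813640, had 3517 and 4057 counts. RNASEH2C stood at 149 ± 7.68 TPM, RNASEH1 at 12.1 ± 0.137 and RNASEH2B at 4.00 ± 0.207. The place of RNASEH2B depends on its deposited exon length of 26222 bases, against 5945 for RNASEH1 and 2056 for RNASEH2A. Without length correction RNASEH2B had 51.9 ± 1.09 CPM, above RNASEH1 at 35.7 ± 0.692. RNASEH2A shares 53.3% of its exonic bases with other genes and RNASEH2C 28.9%, and without such genes 2 members were left with adjusted p = 0.502. The call was also lost among detected genes alone (adjusted p = 0.135).

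The 15 RNA-DNA hybrid helicases were detected throughout, with a median of 13.3 TPM that did not pass the threshold (adjusted p = 0.0561, random-list test). DDX5 led, followed by DDX39B (105 ± 6.14 TPM), DHX9 (88.9 ± 1.94), DDX21 (57.8 ± 13.4) and DDX41 (54.2 ± 1.5). DDX23 had 28.9 ± 0.744 TPM, DDX1 21.1 ± 0.398, DDX19A 13.3 ± 0.876 and BLM 11.1 ± 0.383. PIF1 (9.36 ± 0.381), RTEL1 (8.76 ± 0.91), WRN (3.65 ± 0.514), FANCM (3.20 ± 1.38) and AQR (3.08 ± 0.231) were lower. RTEL1 shares 70.2% of its exonic bases with other genes, DDX39B 30.8% and DDX19A 27.0%, so their values are uncertain. The call was passed with CPM in place of TPM (adjusted p = 0.00679), with the length of the longest coding transcript (0.00762) and without genes that share 25% or more of their exonic bases (0.0374), and the adjusted p ranged from 0.00679 to 0.514 over 7 alternatives. The ribonucleases H lay 1.67 log2 above the helicases, which did not pass the test (exact permutation p = 0.338), and the difference turned to -1.12 log2 without genes that share 25% or more of their exonic bases.

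**Figure D2:**
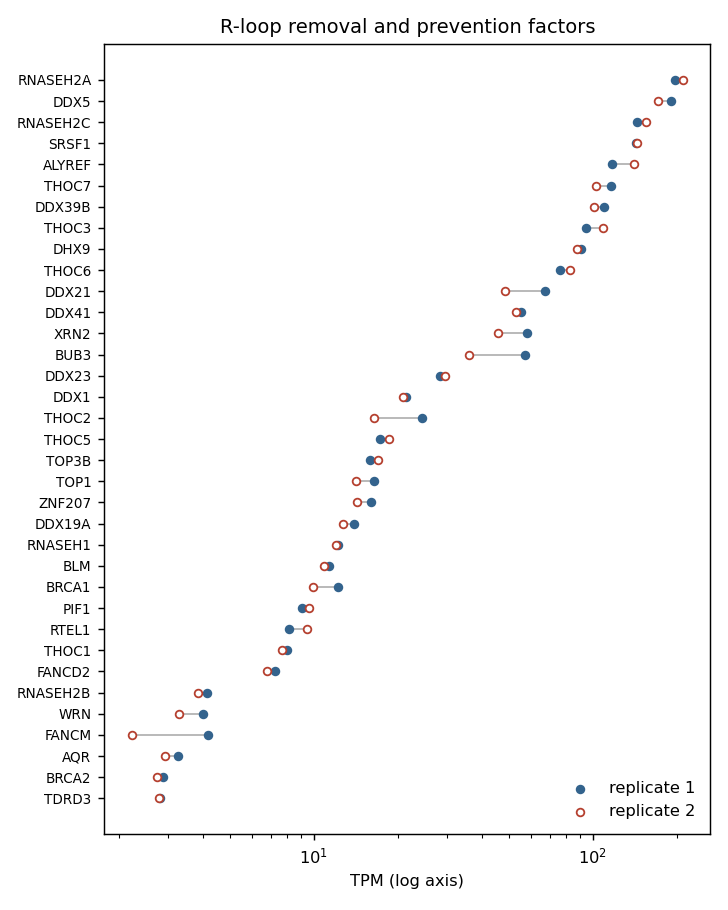
TPM of 35 of the 36 R-loop factors on a log axis, with replicate 1 as filled points and replicate 2 as open points, joined by a line. The factors run from TDRD3 at 2.79 TPM to RNASEH2A at 203 TPM in the mean of both libraries.

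The THO complex and mRNA export genes, which package nascent RNA, had a median of 79.4 TPM, above random lists (adjusted p = 0.000108, random-list test). ALYREF, an export adaptor, had 128 ± 16.3 TPM and NXT1 115 ± 4.76, while NXF1 had 16 ± 2.46 and THOC1 7.85 ± 0.219. All 6 topoisomerases were detected, at a median of 15.8 TPM that did not pass (adjusted p = 0.14). With CPM the list passed (2.88 log2, adjusted p = 0.0279), and over 7 alternatives the adjusted p ranged from 0.0279 to 0.518. TOP2A had 68.8 ± 8.81 TPM, TOP2B 33.9 ± 2.22, TOP3B 16.4 ± 0.844, TOP1 15.2 ± 1.62, TOP1MT 9.61 ± 0.0175 and TOP3A 6.92 ± 0.0686. TOP3B shares 90.8% of its exonic bases with other genes and is uncertain. Homologous recombination and Fanconi anaemia genes had 23 of 24 members detected and a median of 10.1 TPM (adjusted p = 0.0514, not past the threshold). The list passed with CPM (adjusted p = 0.0151), without replicate 2 (0.0434) and without genes that share 25% or more of their exonic bases (0.0425), and over 7 alternatives the adjusted p ranged from 0.0151 to 0.643. FANCL (38.1 ± 16.3 TPM) and FANCG (32.8 ± 0.176) were highest, BRIP1 had 2.72 ± 0.481 and FANCF, at 0.32 ± 0.0405 TPM, was not detected.

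Of 18 genes whose loci serve in R-loop assays, 16 were detected. RPL13A, a ribosomal protein gene at chromosome 19 from 49487510 to 49493057, had 2963 ± 32.2 TPM, ACTB 274 ± 33.9, VIM 218 ± 50.4, APOE 155 ± 10.9 and CALM3 125 ± 4.85. TFPT (44.8 ± 2.73 TPM), MALAT1 (17.6 ± 3.62), ING3 (13 ± 3.22), NEAT1 (11.3 ± 2.23) and FMR1 (7.53 ± 5.97) lay between. TFPT shares 32.8% of its exonic bases with other genes and is uncertain. TRIM33 (6.36 ± 1.95), MYADM (4.87 ± 0.544), C9orf72 (3.60 ± 1.06), ZNF554 (1.89 ± 0.403) and EGR1 (1.12 ± 0.581) were low. BTBD19 had 5 and 3 counts and SNRPN, at chromosome 15 from 24823637 to 24978723, had 0 counts in both libraries. The list's level did not pass against random lists (adjusted p = 0.282, random-list test). FMR1 had 917 counts in replicate 1 and 278 in replicate 2.

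Genes of a dividing cell stood well above the protein-coding median. The DNA replication list, 26 of 26 detected, had a median of 57.1 TPM, led by the sliding clamp gene PCNA (752 ± 55.4) and MCM7 (276 ± 2.28), with POLE (9.91 ± 0.515) and POLA1 (4.41 ± 0.09) lowest. Mitosis and proliferation genes had a median of 48.9 TPM, from CENPE (11.6 ± 2.12) and MKI67 (13.6 ± 0.7) to CCNB1 (180 ± 5.16) and UBE2C (309 ± 59.5). RNA polymerase II subunits had a median of 80.8 TPM, with POLR2L at 298 ± 21.3, POLR2K at 191 ± 2.61, POLR2D at 14.8 ± 0.406 and the largest subunit, POLR2A, at 13.9 ± 0.0202. Core splicing factors had a median of 64.4 TPM, led by SNRPB (1172 ± 48.1) and SNRPD2 (978 ± 91.4). SF3B3 (16.2 ± 0.797) and U2AF1 (3.33 ± 0.196) were lowest, and U2AF1 has a near-identical copy and is uncertain. Each of these 4 lists had adjusted p = 5.83e-05 in the random-list test, whose smallest raw p is 2e-05. The subunits specific to RNA polymerases I and III had a median of 13.5 TPM that did not pass (adjusted p = 0.0544), with POLR1H at 26.5 ± 0.735, POLR3G at 7.14 ± 1.79 and POLR1A at 2.01 ± 0.121.

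Translation and energy genes stood far above the protein-coding median. Ribosomal protein genes had a median of 1346 TPM, from RPL28 (115 ± 7.4) and RPL14 (115 ± 7.19) to RPS2 (7008 ± 412) and RPS12 (8170 ± 14.3). The ends of this range depend on the deposited exon lengths, 6346 bases for RPL28 and 8626 for RPL14 against 639 for RPS12. Without length correction RPL28 had 360 ± 12.2 CPM, RPL14 492 ± 15.6 and RPS12 2584 ± 74.7. The 13 mRNAs of the mitochondrial genome had a median of 2740 TPM, with MT-CO1 at 8301 ± 280, MT-ATP8 at 7912 ± 10.1, MT-CYB at 1162 ± 63.4 and MT-ND5 at 934 ± 21.7. The 2 mitochondrial rRNAs, MT-RNR2 and MT-RNR1, had 2631 ± 244 and 1295 ± 107 TPM. Nuclear genes of the respiratory chain had a median of 127 TPM, led by NDUFA1 (1940 ± 154) and COX5B (750 ± 64.4), with NDUFA9 (13.8 ± 0.245) and NDUFS1 (11.3 ± 0.719) lowest. The mitochondrial mRNAs lay 4.43 log2 above the nuclear list (adjusted p = 2.67e-05, permutation test), and 1.90 log2 above it with CPM (5.33e-05). Glycolysis genes had a median of 192 TPM, with GAPDH at 2162 ± 29.3, TPI1 at 1175 ± 48.8, HK2 at 10.4 ± 0.43 and ALDOC at 7.74 ± 0.58. The 4 protein-coding lists here each had adjusted p = 5.83e-05 in the random-list test.

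**Figure D3:**
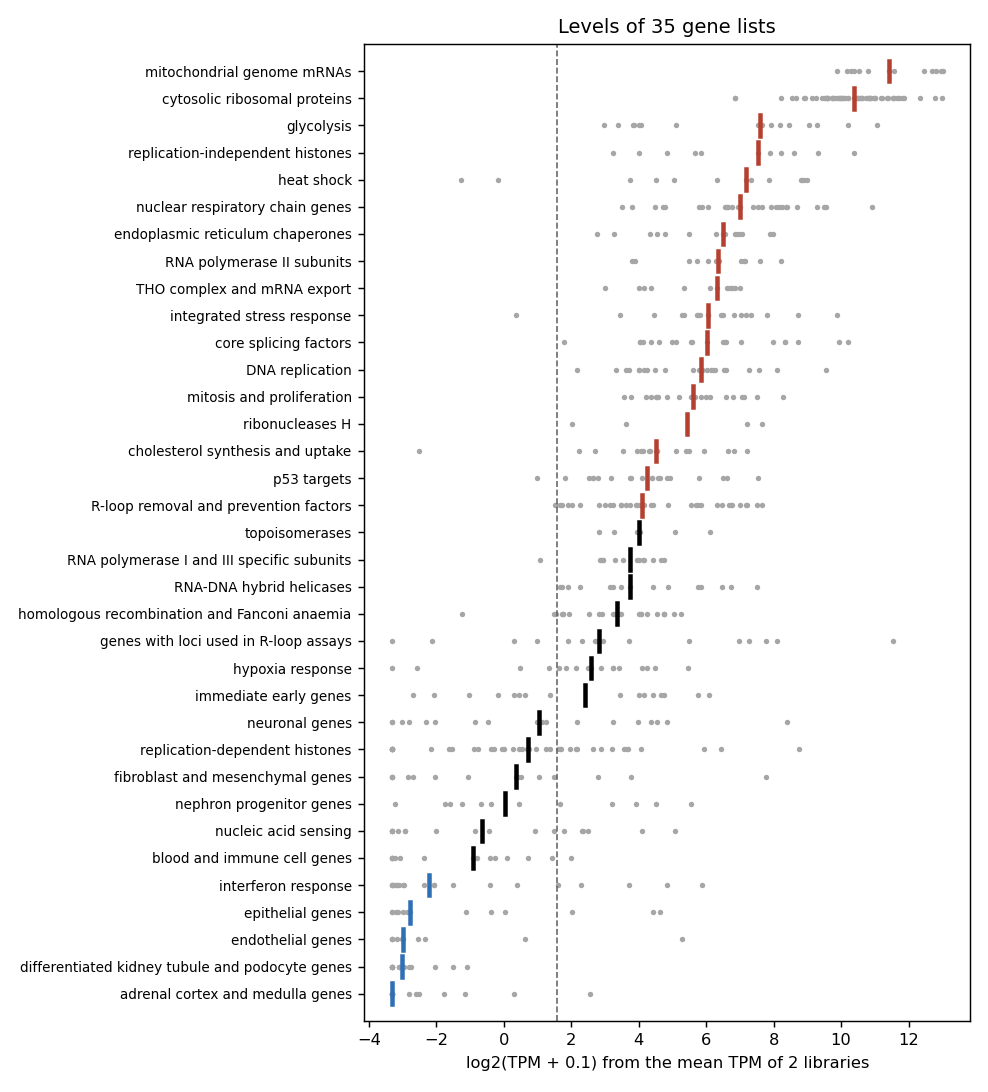
Levels of 35 gene lists as log2(TPM + 0.1), where each grey point is a protein-coding member and each bar is the list's median, red where higher and blue where lower than random lists and black where the adjusted p was not under 0.05. The dashed line marks the median of all protein-coding genes (1.57), and 17 lists are red, 5 blue and 13 black.

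Markers of several differentiated tissues were low, and those of kidney tubules and podocytes among the lowest. Of 15 such kidney genes 1 was detected, LRP2, the megalin gene, at 0.368 ± 0.0679 TPM. AQP1 had 8 and 7 counts, and SLC12A3 and AQP2 had 0. The kidney list, at a median of 0.0229 TPM, differed from the protein-coding median by -4.60 log2 with the pseudocount of 0.1 and by -1.92 log2 with 1 (adjusted p = 0.0101 with either, random-list test), so the size depends on the pseudocount. Adrenal genes had a median of 0 TPM, which leaves no size to give, and were lower than random lists (adjusted p = 0.00354), with 2 of 15 detected. PNMT, which makes adrenaline, had 5.72 ± 0.837 TPM, CHGA 1.12 ± 0.302, and CYP11A1 and CYP11B1 had 0 counts. Epithelial genes (adjusted p = 0.0349) had 5 of 13 detected, with KRT18 at 24.8 ± 2.13 TPM, KRT8 at 21.4 ± 1.69 and KRT5 and KRT14 at 0 counts. Without replicate 2 the epithelial call was lost (adjusted p = 0.0599). Endothelial genes (adjusted p = 0.0245) had 2 of 10 detected, EGFL7 at 39.1 ± 1.77 TPM and ESAM at 1.43 ± 0.139, with ERG and TEK at 0 counts. Among detected genes alone the adrenal, epithelial and endothelial calls were lost (adjusted p = 0.394, 0.514 and 0.9), with 2, 5 and 2 members left.

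Neuronal and nephron progenitor genes were in part present. Of 18 neuronal genes 11 were detected, led by UCHL1 (334 ± 5.81 TPM) and the intermediate filament gene INA (28.3 ± 1.07), while DCX and ELAVL4 had 0 counts. Their median of 1.98 TPM did not pass against random lists (adjusted p = 0.686, random-list test). Of 12 nephron progenitor genes 8 were detected (adjusted p = 0.408), with HOXD11 at 46.9 ± 2.05 TPM, SIX2 at 22.5 ± 1.64, OSR1 at 0.199 ± 0.0252 and PAX8 with 1 and 0 counts. Neuronal genes lay 4.08 log2 above differentiated kidney genes (adjusted p = 0.00235, permutation test), or 1.54 with a pseudocount of 1 (0.00533). They also lay above adrenal genes (adjusted p = 0.00211, and 0.00725 with a pseudocount of 1), with no size given because that median is 0 TPM. Nephron progenitor genes lay 3.05 log2 above differentiated kidney genes, or 0.92 with a pseudocount of 1 (adjusted p = 0.00034 with either). Fibroblast and mesenchymal genes (adjusted p = 0.424, 8 of 15 detected) held VIM and TWIST1 (13.5 ± 3.95 TPM), with COL1A2 and DCN at 0 counts. Blood and immune genes (adjusted p = 0.187) had 2 of 15 detected, among them CD68 (3.89 ± 0.42 TPM), with CD3D and CD3E at 0 counts. CD68 shares 85.6% of its exonic bases with other genes and is uncertain. Without replicate 2 the blood list was lower (adjusted p = 0.0371).

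Interferon response genes were low. Of 20 genes 7 were detected, and the list differed by -3.80 log2 from the protein-coding median (adjusted p = 0.0245, random-list test) and by -8.06 log2 from DNA replication genes (adjusted p = 2.67e-05, permutation test). With a pseudocount of 1 these were -1.80 and -5.70 log2. IFI6 had 58.0 ± 11.1 TPM and ISG15 28.7 ± 3.75, while IFNB1, which encodes interferon beta, and IFI44 had 0 counts. With the 7 detected members alone the list's call was lost (adjusted p = 0.52). Of 18 nucleic acid sensing genes 10 were detected (adjusted p = 0.184), led by IRF3 (33.3 ± 2.72 TPM) and ADAR (17.1 ± 0.853), with AIM2 and TLR7 at 0 counts. CGAS, the cytosolic DNA sensor gene, had 1 and 0 counts, and STING1 had 83 and 71; both were chosen after their values were seen.

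Several stress lists stood above random lists. Integrated stress response genes had a median of 66.9 TPM, with ATF4 at 932 ± 10.2, PSAT1 at 424 ± 33.7, SLC7A11 at 10.7 ± 1.07 and VLDLR at 1.18 ± 0.103. Endoplasmic reticulum chaperones had a median of 90.6 TPM, with CALR at 253 ± 29.7, SDF2L1 at 239 ± 6.86, DNAJB9 at 9.60 ± 1.83 and DNAJC3 at 6.71 ± 0.179. Heat shock genes had a median of 145 TPM, with HSP90AB1 at 506 ± 9.24 and HSPA8 at 480 ± 3.53. HSPA6 (0.781 ± 0.622) and HSPA1A (0.318 ± 0.113) were not detected, and HSPA1A is uncertain because HSPA1B (79.7 ± 5.16 TPM) is nearly identical. HSPA1B also shares 36.6% of its exonic bases with other genes. Each of these 3 lists had adjusted p = 5.83e-05 in the random-list test. All 20 p53 targets were detected (adjusted p = 0.00535, random-list test), from ZMAT3 (1.86 ± 0.554 TPM) and FAS (3.40 ± 0.108) to BAX (97.9 ± 10.9) and PMAIP1 (186 ± 52.4). FAS shares 40.6% of its exonic bases with other genes and is uncertain. Cholesterol synthesis and uptake genes (adjusted p = 0.00243) were led by FDPS (147 ± 8.76 TPM) and PMVK (114 ± 12.1). Immediate early genes (adjusted p = 0.46) held JUN (67.7 ± 5.29 TPM) and JUND (53.5 ± 10.5), with EGR2 and EGR3 not detected. Hypoxia genes (adjusted p = 0.393) held BNIP3 (43.9 ± 6.86 TPM) and P4HA1 (22.4 ± 0.441), with CA9 at 1 and 1 count and ANGPTL4 at 0. The p53 and cholesterol calls were lost among detected genes alone (adjusted p = 0.126 and 0.0687).

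Transcripts without a poly(A) tail took few of the counts, in libraries primed with oligo(dT). Replication-dependent histone genes, whose mRNAs end in a stem-loop, differed from the replication-independent ones by -6.82 log2 (adjusted p = 2.67e-05, permutation test, whose smallest raw p is 1e-05). The 42 replication-dependent genes took 0.0229% ± 0.00102 of the counts, and the 11 others took 0.487% ± 0.0289. H2BC12 (428 ± 22.2 TPM) and H1-2 (86.2 ± 1.2) were the highest of the first list and H1-1 and H2AC14 had 0 counts. In the second list H2AZ1 had 1346 ± 58.7 TPM, H3-3A 635 ± 111, H2AJ 15.8 ± 0.798 and MACROH2A2 9.39 ± 0.768. Against random lists, the replication-dependent genes did not pass (-0.85 log2, adjusted p = 0.381) and the replication-independent ones were higher (adjusted p = 5.83e-05). With CPM, which does not correct for length, the replication-dependent list was lower and passed (-3.73 log2, adjusted p = 0.0142), and over 7 alternatives its adjusted p ranged from 0.0142 to 0.682.

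Among 24 noncoding RNAs without a tail 5 were detected, and the 24 took 0.00587% ± 0.000684 of the counts. Neither value corrects for length. In TPM the median of the 24 was 3.98, which was not below the 2.88 TPM of all protein-coding genes. RN7SL1, the RNA of the signal recognition particle, had 656 and 807 counts and RN7SK 112 and 116, while RNU1-1 and RNU4-1 had 0. RN7SK lies wholly within exons of another gene and is uncertain. Of 17 long noncoding RNAs with a tail 15 were detected, led by SNHG6 (324 ± 39.8 TPM) and GAS5 (207 ± 5.74), with KCNQ1OT1 at 0.0608 ± 0.00107 and MEG3 at 0 counts. SNHG6 shares 36.4% of its exonic bases with other genes and is uncertain. The first list differed from the second by -2.23 log2 (adjusted p = 0.0433, permutation test), and by -7.50 log2 with CPM (6e-05), which does not correct for length. This call was lost with means (adjusted p = 0.0968), without replicate 1 (0.0888) and without genes that share 25% or more of their exonic bases (0.514).

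Between the replicates, 3 of 33 gene lists lay in the outer 5% of random lists. Of the lists with 3 or more members at a mean count of 50, 1 lay in the lowest 2.5% and 2 in the highest 2.5% of 10000 random lists matched on mean expression, where chance puts 5% in both tails together. Genes with loci used in R-loop assays had a median log2 ratio of -0.31, at percentile 0.02. That median is the ratio of NEAT1, which is noncoding, as is MALAT1, while the random lists held protein-coding genes alone. Core splicing factors had 0.15 (percentile 98.9) and glycolysis genes 0.16 (98.8). R-loop factors had 0.02, at percentile 51.4. After centring on transcript GC content, an alternative chosen after seeing the data, the assay genes had -0.12 at percentile 1.64, core splicing factors 0.11 at 97.98 and R-loop factors 0.07 at 95.8. Glycolysis genes were then no longer outside (0.11, percentile 96.8), while endoplasmic reticulum chaperones were (0.17, percentile 99.8). With total counts as the scaling, the chaperones also lay just outside (percentile 97.52).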

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

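The tests in this part were chosen after the results were seen, except the simulation of counting noise, which was set before its outcome was known, and the counts of genes at a mean count of 200 or more, an alternative fixed before the data were examined.

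A few loci had reads in 1 library alone, with 0 counts in the other and 20 or more here. In replicate 2 these were PEAK3 (153 counts), ENSG00000268375 (96), HLA-H (42), HBB (38) and OR51V1 (27), and in replicate 1 MIR1279 (31). MIR1279 and HLA-H share exonic bases with other genes, and OR51V1 lies 24782 bases from HBB. In 100 simulated pairs of unchanged libraries with a coefficient of variation of 20%, 0 gave as many as 6 such genes. This argues against counting noise of independent reads. Many reads copied from 1 molecule were not simulated, so the simulation cannot exclude them. The other 3716 protein-coding genes with no count in replicate 1 had 0.113 counts per kb of exons in replicate 2, against 28.5 at OR51V1, the least dense of the 5 loci (lower 95% Poisson bound 18.8), which argues against genomic DNA spread over the genome. Genomic DNA of the surrounding 50 kb is argued against at PEAK3, ENSG00000268375 and HLA-H. The neighbours of all 5 loci were other genes within 50 kb with fewer than 10 counts in replicate 1, 4 to 11 per locus. They reached the counts per kb of their locus at 0 of 5 loci (upper 95% Poisson bounds from 0.461 to 6.76, against lower bounds of the loci from 18.8 to 299). Of those with no count in replicate 1, 22 in all, 0 had counts in replicate 2. The 5 loci themselves were left out as neighbours, so a silent gene reaching 20 counts could not enter the 22. At PEAK3 the comparison rests on 4 neighbours, of which 0 were silent, with 14 and 29 counts together. It left out strongly counted genes there, such as OAZ1 at 1141 bases (20444 and 22220 counts). ENSG00000273734, whose span overlaps PEAK3, was also left out (10008 and 13109 counts). PEAK3 shares 0% of its exonic bases with other genes. Whether its reads came from transcripts of such neighbours was not tested. HBB and OR51V1 lie within 50 kb of each other and both had counts in replicate 2 alone, so the test cannot decide there. Blood cells cannot be told apart as a source of the HBB reads. HBA1, HBA2, HBD, ALAS2, AHSP and SLC4A1 gained 9 counts together, but 31.9% of 50-base stretches of HBA1 and HBA2 occur in no other gene, which lowers the bound from 26.9 to 8.58 counts. DNA fragments or a plasmid holding these 5 loci of replicate 2 also stay open without read positions. Apart from blood cells for HBB, no biological explanation was tested.

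Genes of the antisense type held 4.06% of the counts in replicate 1 and 4.24% in replicate 2, and no list above measured them as a group. Of 5542 such genes 3241 share exonic bases with another gene, and these held 98.1% and 98.3% of the antisense counts. Genes of the type that share 25% or more held 78.6% and 78.3%. The median count was 14 and 15 for antisense genes with shared bases, against 0 in both libraries for those without. The counts behaved as if reads were given to each overlapping gene whatever its strand. Most antisense counts therefore cannot be told apart from reads of the overlapping genes.

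More genes were lower than higher in replicate 2. Of 11721 protein-coding genes with a mean count of 50 or more and an annotated 3' UTR, 238 were lower and 6 higher by 1 log2 or more. The ratio followed the GC content of the 3' UTR (Spearman's rho 0.486 across genes, which are not independent), and lower genes had a median 3' UTR GC of 32.0% against 42.5% for all. Of the 238 lower genes, 184 lay in the lowest quintile of 3' UTR GC. Centring on transcript GC left 122 lower and 10 higher, and centring on 3' UTR GC and length left 86 and 8. Centring removes only the median shift of each bin and not a wider or skewed spread within it. The genes left over therefore cannot decide whether either trend was the whole cause. The median of the lower genes moved from -1.26 to -1.0 and -0.85 log2 with these 2 centrings, which goes with the 3' UTR trend being at least a part of the asymmetry. Counting noise is argued against, as 154 genes were lower and 2 higher at a mean count of 200 or more. What stays open is how much of the asymmetry the GC trends carry. A difference in library preparation or culture, which the labels do not give, also stays open, and no biological explanation was tested.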

How the results depend on the processing

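The alternatives that centre on GC content, leave out genes sharing 25% or more of their exonic bases (below, overlapping genes) or use another transcript length were chosen after seeing the data. Detected genes ranged from 13372 to 18444, within 1.5 times of 16801. Pearson's r was 0.982 with a pseudocount of 0.1, 0.991 with 5, 0.995 with no filter and 0.983 at 100 or more counts, and Spearman's rho was 0.930 with no filter and 0.980 at 100 or more counts. The coefficient of variation was 15.48% with DESeq2 size factors, 16.17% with no filter, 15.39% at a mean count of 50 or more and 15.49% without overlapping genes. The 10 most counted genes held 4.89% once mitochondrial genes were dropped from the 10 and from the total. No list was lower (0) when pool and lists were limited to detected genes, by construction, since most members of those lists were undetected. For list levels, 225 calls were the same, 9 newly passed and 10 were lost.

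Genes higher and lower in replicate 2 numbered 214 and 562 at a mean count of 10 or more, 2 and 154 at 200 or more, and 1172 and 2257 with no filter. The cause was not tested, though the spread was wider at low counts. Centring on GC content left 164 lower and 31 higher. The difference between noncoding RNAs without and with a tail was -1.83 with means (adjusted p = 0.0968) and -1.53 without overlapping genes (0.514), ranged from -2.43 to -1.66 without replicate 1 or 2, and was -7.50 with CPM (6e-05). Without overlapping genes, the ribonucleases H fell below the helicases (-1.12, exact permutation p adjusted to 0.571), with 2 of 4 members left. The cause was not tested for the means and the left-out replicate. The other 6 list pairs kept their direction and call under the 6 alternatives run for pairs, which were CPM, pseudocount 1, means, either replicate left out and no overlapping genes. Their sizes moved, with the mitochondrial mRNAs at 1.90 with CPM in place of 4.43, and with neuronal and nephron progenitor genes at 1.54 and 0.92 over kidney genes with pseudocount 1 in place of 4.08 and 3.05. Depth limits genes near 0, since a count of 0 allows up to 0.167 CPM in replicate 1 and 0.162 CPM in replicate 2. No paired analysis was possible because there is only 1 group.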

Other observations

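Paternally expressed genes of the imprinted domain 15q11-q13 were nearly silent. These genes were listed after SNRPN was seen at 0. Of 9 genes 1 was detected, the noncoding SNHG14 (114 and 38 counts), and 6 had 0 counts in both libraries, SNRPN, SNURF, NDN, NPAP1, PWAR1 and PWAR5. SNHG14 shares 11.5% of its exonic bases with other genes, so its counts are uncertain. MKRN3 had 19 and 4 counts and MAGEL2 5 and 4. All 7 neighbours that are not paternally expressed were detected, UBE3A with 605 and 410 counts, CYFIP1 with 1027 and 1031, and TUBGCP5, NIPA1, NIPA2 and HERC2 among the others. Of 13 paternally expressed genes elsewhere 4 were detected, SGCE, PLAGL1, ZDBF2 and L3MBTL1.

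The test of copies was set before its outcome was known and the comparison with genes elsewhere after. Over the 8 undetected genes, the median share of 50-base stretches that also occur in transcripts of genes outside the domain was 0.01%, and the highest was 2.30% (PWAR5), which argues against reads lost to annotated near-identical copies. Silence of paternally expressed genes in general cannot be told apart from an effect of this domain, since detection elsewhere did not differ past the threshold (Fisher's exact p = 0.36, two-sided) with few genes, some of which overlap. A silenced or absent paternal allele was not tested, and would need DNA methylation, copy number or allele-specific reads.

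The median ratio between the libraries ran from -0.18 log2 on chromosome 13 (206 genes) to 0.10 on chromosome 19 (865 genes) over the chromosomes analysed. After centring on transcript GC content, chosen after seeing the data, it ran from -0.05 to 0.03 on the same 2 chromosomes.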
